A study of Homo sapiens with 18 samples.

How the data were processed

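RNA was measured in 18 libraries of 2 human lymphoma cell lines, Ly1 and U2932, in 6 groups of 3: DMSO, and SGC-GAK-1 at 1 µM for 12 h and for 24 h, in each line. Per the labels' protocols the libraries were made with the NuGEN Universal Plus mRNA-Seq kit, with 14 PCR cycles, and sequenced on a NovaSeq instrument in 2 runs whose reads were combined. Per the submitters' processing notes, the authors trimmed reads with cutadapt, aligned them with STAR to hg38 and used Picard. Their versions, the counting tool, the use of strand, the annotation release and the treatment of duplicate reads are not given in the sources used here. The deposited table holds read counts per gene for 60656 genes, as whole numbers, of which 27386 are 0 in all libraries. Total counts of replicates 1, 2 and 3 in Ly1 were 29386802, 25024892 and 22549853 in DMSO, 23624860, 24851943 and 26047460 at 12 h and 23411186, 26013518 and 25296489 at 24 h. In U2932 they were 26316407, 24703651 and 26030550 in DMSO, 23898995, 24757893 and 23937545 at 12 h and 23592166, 23856414 and 23236970 at 24 h. Gene names, types and coordinates are those of the deposited table. Raw reads were not used here.

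Genes were tested with edgeR 4.0.16, with TMM scaling, the filter filterByExpr, robust dispersions, the quasi-likelihood F test and Benjamini-Hochberg adjustment, at an adjusted p of 0.05. Each line was fitted on its own, with its 9 libraries in 3 groups that share an estimate of the spread, and the differences between lines in their response and in DMSO were fitted on all 18. Of the genes, 14005 were tested in Ly1, 15138 in U2932 and 16191 in both. Standard errors of log2 fold changes come from the same fits. CPM are the deposited counts scaled to a common library total with TMM factors. R was 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

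Gene lists were written by hand before the data were examined, and so were the groups, the comparisons, the tests, the other settings to try and the rule for named genes. The 32 lists cover G2 and mitosis, the spindle assembly checkpoint, the centrosome, tubulins, replication-dependent histones, S phase and DNA replication, G1 to S regulators of the RB and E2F axis, p53 targets, heat shock, the unfolded protein response, ATF4 targets, NF-kappaB targets, interferon-stimulated genes, immediate early genes, cholesterol synthesis, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation genes, mitochondrially encoded mRNAs, ribosomal proteins, ribosome biogenesis, the lysosome, clathrin and endocytosis, coenzyme Q synthesis, the BCL2 family, B cell identity, germinal centre, activated B cell type and plasma cell markers, and markers of T and NK, myeloid, fibroblast and endothelial, and epithelial cells. A list was tested with at least 5 expressed genes, which left 29. The test was camera of limma on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The median log2 fold change of the members and its value within each replicate number are given beside it. Because camera with the preset correlation takes genes of a list as nearly independent, each call is given again with a correlation estimated per list, and members were also adjusted over the list alone.

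Named genes were chosen by a fixed rule. For each comparison these are up to 8 genes with the largest rise and 8 with the largest fall (5 and 5 between treated times and for differences between lines) among genes with an adjusted p under 0.05, a mean of at least 5 CPM in the higher group, a gene symbol, and no overlap between the libraries of the groups. For calls with the block, a rule added after the data were seen asks for the same sign in each replicate number instead. Up to 4 members of a list past its test were added, and 11 fixed genes: GAK, CCNG1, AAK1, BMP2K, DNAJC6, RIPK2, COQ8A, RB1, CDKN1A, CCNB1 and MYC. Genes with several near-identical copies, pseudogenes, and noncoding genes that can share reads with the other strand are reported as uncertain. Of the genes this rule picked, 1 is not reported here.

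The labels give the groups the same replicate numbers without saying what a number stands for. Whether numbers pair libraries was checked from the correlation over genes of the deviations from group means between libraries of the same number. A pairing required all 3 correlations above 0.1. They were 0.213 to 0.434 for Ly1 12 h and DMSO, 0.1 (just above the limit before rounding) to 0.332 for Ly1 24 h and 12 h, 0.073 to 0.211 for Ly1 24 h and DMSO, 0.38 to 0.666 for U2932 12 h and DMSO, 0.336 to 0.563 for U2932 24 h and DMSO, and 0.374 to 0.649 for U2932 24 h and 12 h. Numbers therefore paired all comparisons but Ly1 24 h and DMSO, from the data and not from the labels, and values with replicate number as a block are given where they change a call or a count of a paired comparison.

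The alternatives tried were DESeq2's size factors and library size in place of TMM, no filter and a filter of at least 1 CPM in 3 libraries, DESeq2 and limma voom in place of edgeR, the replicate block, fits of the 2 compared groups, a required 2-fold change, an estimated correlation and the rotation test fry for lists, and leaving out each library in turn. Fits with a term for replicate 3, without the replicate 3 libraries, with the block in other tools, and with the block and all libraries of a number left out were added after the data were seen. Where libraries were fewer, the spread was pooled over the groups of a fit. The groups were also split in all other ways into 3 and 3, and in 24 drawn ways for the differences between lines. The correlation that shared DMSO libraries give without any effect was measured on simulated unchanged groups.

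The fits were tested on simulated data with the means and library sizes of the real groups and 200 genes changed by 1.5-fold, 2-fold or 4-fold. For Ly1 24 h against DMSO, with replicate differences as fitted, edgeR without the block recovered 17.9, 62.7 and 83.3 percent of them, with 0 percent of calls false. For U2932 24 h against DMSO it recovered 14.9, 70.1 and 87.9 percent, and with the block 59.7, 89.6 and 95.5 percent, with 0.9 and 9.9 percent of calls false. Without replicate differences, 6, 37.3 and 65.2 percent were recovered for the difference between lines at 24 h, and 25.4, 53.7 and 78.8 percent for the lines in DMSO. At 24 h in Ly1 numbers did not pair, so its 0 percent may not hold for real data.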

Results

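Messenger RNA was sequenced from 2 human lines of diffuse large B cell lymphoma, a tumour of mature B cells. Ly1 is described by the submitters as germinal centre B cell-like (GCB) and U2932 as activated B cell-like (ABC). Cells received SGC-GAK-1 at 1 µM for 12 h or 24 h, or the solvent DMSO. SGC-GAK-1 is a small-molecule inhibitor of GAK, the cyclin G-associated kinase. GAK acts in the uncoating of clathrin-coated vesicles and also at the mitotic spindle and centrosome. Each of the 6 groups held 3 libraries, numbered as replicates 1 to 3, and no time was given for the DMSO libraries, so the same 3 served both treated times of a line. At the depth of these libraries 3 counts, the upper limit that a count of 0 allows, stand for 0.102 to 0.133 CPM (counts scaled to a common library total), for counting error only. Adjusted p-values of genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and those of gene lists from camera, unless another tool is named. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples.

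The replicate 3 libraries stood apart from replicates 1 and 2 in both lines. In U2932, 20 genes of at least 20 CPM were at least 4-fold lower in replicate 3 than in the mean of replicates 1 and 2 in each of the 3 groups. By that factor 0 were higher, and 0 differed between replicates 2 and 1. These genes were chosen after their values were seen. MYC, the transcription factor of growth and proliferation (ENSG00000136997.20, chromosome 8, 127735434 to 127742951), stood at 331, 351 and 50.6 CPM in DMSO replicates 1, 2 and 3 of U2932. VIM, which encodes the intermediate filament vimentin, stood at 80.8, 86.7 and 10.1 CPM, and CCND2, which encodes cyclin D2, at 47.5, 56.8 and 6.91 CPM. ROR1, a receptor tyrosine kinase-like protein, gave 34.4, 33.2 and 3.28 CPM. Genes of G2 and mitosis were also lower in U2932 DMSO replicate 3, with a median log2 difference of -1.10 from replicates 1 and 2. In Ly1, DMSO replicate 3 had higher glycolysis and hypoxia genes (median 0.88), NF-kappaB targets (0.67) and G2 and mitosis genes (0.48), and lower heat shock genes (-0.45). Across 7362 genes of Ly1, the change from DMSO to 24 h correlated between replicates 1 and 2 with r = 0.92 and between replicates 1 and 3 with r = -0.15. Across 7672 genes of U2932 these values were 0.65 and 0.28, and genes are not independent replicates. For the first gene groups of each comparison within a line, the change within each replicate number is therefore given beside the fitted one. A library left out is in places named by group and number alone, as DMSO 3, with the median without it in parentheses, and medians said to have moved did so by over 1.5 times.

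**Figure D1:**
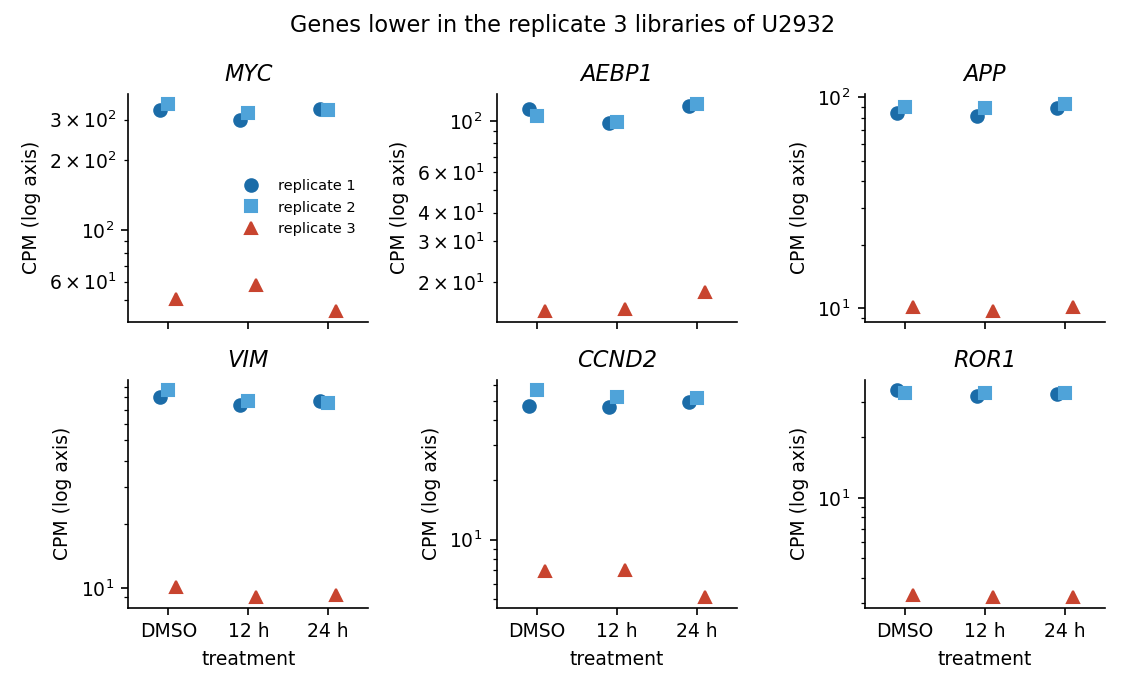
CPM of 6 genes in each U2932 library, on log axes, by treatment, with a point per library and no error bars. In each of the 3 groups the replicate 3 library lies below replicates 1 and 2, as for MYC in DMSO, at 50.6 against 331 and 351 CPM.

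GAK itself was higher in U2932 than in Ly1, at 62.8 ± 0.947 against 41.5 ± 0.929 CPM in DMSO (mean ± SD, n = 3 each), a log2 difference of 0.60 ± 0.08 (SE, adjusted p = 1.99e-06). Its level did not pass the test after treatment, with a log2 fold change at 24 h of 0.05 ± 0.08 (SE) in Ly1 (adjusted p = 0.802) and 0.11 ± 0.08 in U2932 (0.623). The related kinases AAK1 and BMP2K, which act in clathrin-mediated endocytosis, and RIPK2, a kinase of innate immune signalling, also missed the threshold at 24 h. Their values were -0.33 ± 0.13, 0.13 ± 0.14 and 0.14 ± 0.08 in Ly1 and 0.10 ± 0.10, 0.10 ± 0.12 and -0.05 ± 0.11 in U2932 (adjusted p from 0.259 to 0.903). Genes of clathrin and endocytosis as a list had medians of -0.024 in Ly1 and 0.002 in U2932 at 24 h (adjusted p = 0.646 and 0.877). Of the cell-cycle regulators followed, the CDK inhibitor CDKN1A had a log2 fold change of -0.47 ± 0.19 in Ly1 (adjusted p = 0.254) and 0.06 ± 0.12 in U2932 (0.883), and RB1 had -0.55 ± 0.21 in Ly1 (0.238) and 0.16 ± 0.09 in U2932 (0.561), so neither passed.

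The comparison of Ly1 at 24 h with DMSO asks what inhibition of GAK changes in the GCB line, and genes of mitosis were higher after treatment. CCNB1, which encodes cyclin B1, the partner of CDK1 at entry into mitosis (ENSG00000134057.15, chromosome 5, 69167135 to 69178245), rose from 133 ± 44.5 to 313 ± 55.0 CPM (mean ± SD, n = 3 each), a log2 fold change of 1.24 ± 0.20 (SE, adjusted p = 0.0392). KIF20A (ENSG00000112984.12, chromosome 5, 138178719 to 138187723), a kinesin of cytokinesis, rose by 1.21 ± 0.19 (log2, SE). CENPA, the histone H3 variant of centromeres, rose by 1.15 ± 0.16, AURKA, a kinase of centrosome and spindle, by 1.11 ± 0.18, and PTTG1, which encodes securin, by 1.01 ± 0.19 (adjusted p from 0.0392 to 0.0489). In replicates 1, 2 and 3 the change of CCNB1 was 1.74, 1.63 and 0.44. The other top rises were HSPA2, of the HSP70 family (1.23 ± 0.21), MX1, an interferon-induced GTPase (1.08 ± 0.19), and MT-ATP8, a mitochondrially encoded subunit of ATP synthase (1.05 ± 0.19). ALDOC, the glycolytic enzyme aldolase C (ENSG00000109107.14, chromosome 17, 28573115 to 28576948), had the largest fall, with -2.04 ± 0.36 (adjusted p = 0.0451). In replicates 1, 2 and 3 it was -1.27, -1.38 and -2.91, and the fitted value was -1.35 without DMSO replicate 3. ITGB2, the beta chain of leukocyte integrins, fell with -1.43 ± 0.25 and ST3GAL1, a sialyltransferase (ENSG00000008513.16, chromosome 8, 133454848 to 133571940), with -1.22 ± 0.13 (adjusted p = 0.0221). LINC02532, C10orf71, the septin SEPTIN8, the protease FURIN and the tropomyosin TPM4 fell with log2 fold changes of -1.06 ± 0.15, -0.98 ± 0.14, -0.97 ± 0.18, -0.93 ± 0.17 and -0.88 ± 0.12 (largest adjusted p 0.0488). In all, edgeR called 77 of 14005 genes, 48 higher and 29 lower, with DESeq2 calling 573 and limma voom 61. Each of these calls ended, with 0 genes called, when DMSO replicate 1, DMSO replicate 2, 24 h replicate 1 or 24 h replicate 2 was left out. The count was 807 without DMSO replicate 3, 3030 without 24 h replicate 3, and 6483 without the replicate 3 libraries. It was 1 with library size only and 0 with only the 2 compared groups.

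**Figure D2:**
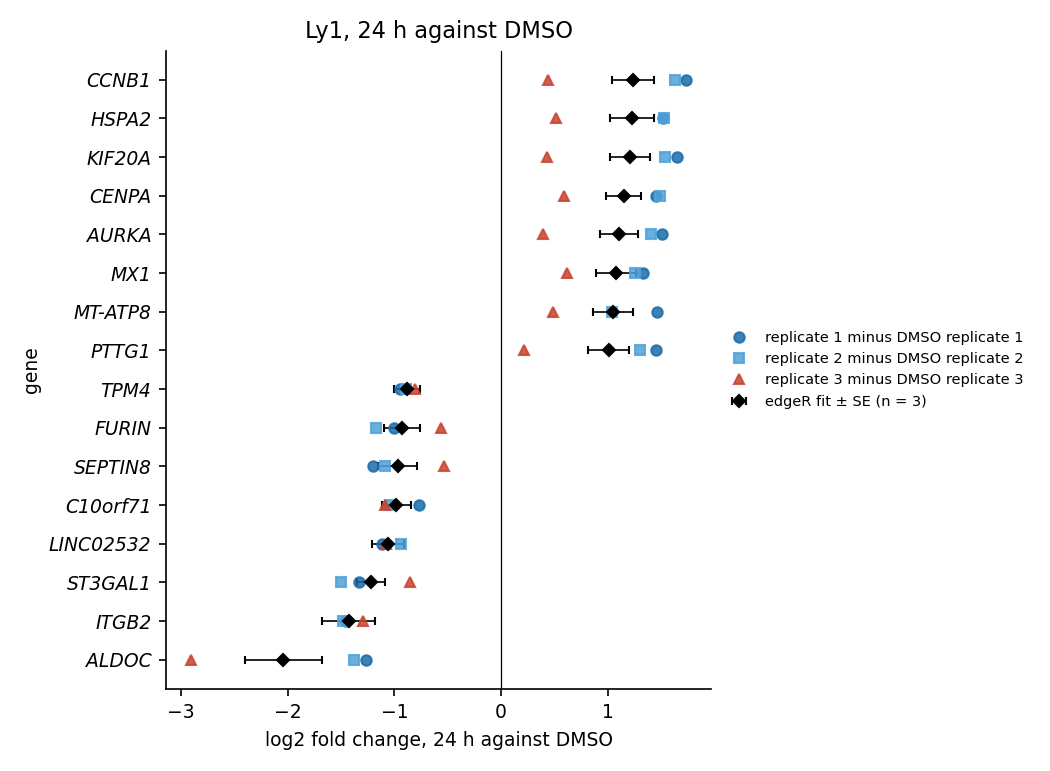
Log2 fold change of the named genes of Ly1, 24 h against DMSO. Diamonds with bars are the edgeR estimates ± SE (n = 3 per group) and the other points are the differences within each replicate number. The common sign of the replicate numbers follows from the choice of genes, which required no overlap between the groups. CCNB1 was at 1.74, 1.63 and 0.44 in replicates 1, 2 and 3.

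As a group, the genes of G2 and mitosis rose in Ly1 at 24 h, with a median log2 fold change of 0.63, 53 of 54 members above 0. Of these, 17 were called over all genes and 47 when adjusted over the list alone (list adjusted p = 6.87e-31 by camera, adjusted p = 0.227 with an estimated correlation). Within replicates 1, 2 and 3 the median was 0.83, 0.84 and 0.30. Spindle assembly checkpoint genes had a median of 0.43 (adjusted p = 1.05e-06, adjusted p = 0.172 with an estimated correlation, 0.35, 0.67 and 0.31 by replicate). CDC20, TTK, AURKB and BUB1B were called in it at 0.90 ± 0.12, 0.65 ± 0.11, 0.87 ± 0.15 and 0.59 ± 0.11. Lists can share genes, so their rises are not separate evidence. Centrosome genes rose by a median of 0.30 (0.48, 0.42 and 0.07 by replicate, adjusted p = 7.54e-06, adjusted p = 0.227 with an estimated correlation), with NEK2 and CEP55 at 0.81 ± 0.13 and 0.85 ± 0.13. Its median was 0.18 without DMSO replicate 1. Tubulins rose by a median of 0.35 (0.39, 0.43 and 0.28 by replicate, adjusted p = 1.53e-07, adjusted p = 0.172 with an estimated correlation). TUBA1C and TUBB4B were called at 0.62 ± 0.09 and 0.70 ± 0.12. Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, rose by a median of 0.64 with 27 of 27 members above 0. Over all genes 0 were called, against 5 adjusted over the list alone (adjusted p = 6.16e-08, adjusted p = 0.309 with an estimated correlation, 0.73, 0.75 and 0.19 by replicate).

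Mitochondrially encoded mRNAs rose in Ly1 at 24 h by a median of 0.71, with 13 of 13 members above 0. Of these 1 was called over all genes (MT-ATP8) and 13 adjusted over the list alone (adjusted p = 2.56e-07, adjusted p = 0.536 with an estimated correlation). Their change in replicates 1, 2 and 3 was 1.01, 0.72 and 0.24. Interferon-stimulated genes rose by a median of 0.42 (0.51, 0.35 and 0.11 by replicate), with 1 called over all genes and 8 adjusted over the list alone (adjusted p = 3.28e-05, adjusted p = 0.309 with an estimated correlation). Glycolysis and hypoxia genes fell, with a median of -0.56, 28 of 28 members below 0. ALDOC was called over all genes and 6 were called when adjusted over the list alone (adjusted p = 1.41e-06, adjusted p = 0.75 with an estimated correlation). This fall was -0.27, -0.26 and -0.95 in replicates 1, 2 and 3, beside the higher level of the same genes in DMSO replicate 3. The median moved to -0.11 without DMSO replicate 3. Members that were not called include PGK1, phosphoglycerate kinase, at -0.74 ± 0.22, and BNIP3, a mitophagy receptor, at -0.93 ± 0.26 (adjusted p = 0.157 and 0.132). Without DMSO replicate 3 they stood at -0.35 and -0.45, and BNIP3 was then called (adjusted p = 0.0476). Heat shock genes had a median of 0.32 (0.23, 0.17 and 0.51 by replicate), with the HSP90 cochaperone CHORDC1 called at 0.78 ± 0.15 (adjusted p = 0.000112 for the list, adjusted p = 0.546 with an estimated correlation). They did not pass without DMSO 3 (0.17). Targets of ATF4 and the integrated stress response had a median of 0.32 (0.20, 0.24 and 0.30 by replicate, adjusted p = 0.000825, adjusted p = 0.487 with an estimated correlation). They did not pass without 24 h 3 (0.23), and moved without DMSO 2 (0.17). Nuclear-encoded genes of oxidative phosphorylation had 0.19 (0.26, 0.21 and 0.12 by replicate, adjusted p = 0.00122, adjusted p = 0.878 with an estimated correlation). The list did not pass without DMSO 3 (0.13), and moved without 24 h 1 (0.11) and 3 (0.33).

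At 12 h in Ly1 the genes of G2 and mitosis were already higher as a group, with a median log2 fold change of 0.46 and 54 of 54 members above 0 (adjusted p = 6.11e-41, adjusted p = 0.174 with an estimated correlation). Over all genes 0 members were called, and 38 were called when adjusted over the list alone. The median was 0.62, 0.62 and 0.20 in replicates 1, 2 and 3. CDC20, the activator of the anaphase-promoting complex (ENSG00000117399.14, chromosome 1, 43358981 to 43363203), stood at 241 ± 14.8 against 149 ± 21.6 CPM in DMSO (mean ± SD, n = 3 each). Its log2 fold change was 0.70 ± 0.12 (SE, adjusted p = 0.25). BIRC5, which encodes survivin, had 0.63 ± 0.11 (0.25). Spindle assembly checkpoint genes rose by a median of 0.49 (0.57, 0.64 and 0.22 by replicate, adjusted p = 1.17e-10, adjusted p = 0.0802 with an estimated correlation). Tubulins rose by 0.31 (0.31, 0.29 and 0.31 by replicate, adjusted p = 5.39e-07, adjusted p = 0.174 with an estimated correlation) and centrosome genes by 0.17 (0.32, 0.39 and 0.09 by replicate, adjusted p = 3.5e-06, adjusted p = 0.182 with an estimated correlation). The median became 0.37 without DMSO replicate 3. Glycolysis and hypoxia genes had a median of -0.46 with 28 of 28 below 0 (adjusted p = 4.66e-08, adjusted p = 0.736 with an estimated correlation). By replicate it was -0.05, -0.06 and -0.99 in 1, 2 and 3. The call ended without DMSO replicate 3 (median -0.022, adjusted p = 0.115). Gene by gene, edgeR called 0 genes, with 858 at an unadjusted p under 0.05 and a smallest adjusted p of 0.232. DESeq2 called 94 and limma voom 0, and leaving out DMSO replicate 3 gave 88 by edgeR.

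Smaller shifts passed the list test in Ly1 at 12 h. Cholesterol synthesis genes had a median of 0.24 (adjusted p = 0.000239), p53 targets 0.19 (0.00396), heat shock genes 0.19 (0.000161) and S phase genes 0.099 (3.08e-05). Mitochondrially encoded mRNAs had a median of 0.23 (0.00644) and ribosomal protein genes -0.081 (0.0454). With an estimated correlation 0 of the 11 list calls at 12 h remained (adjusted p = 0.0802 to 0.838). Cholesterol synthesis genes moved without 12 h 3 (0.12). The p53 targets did not pass without DMSO 2 (0.12). Heat shock genes did not pass without DMSO 3 (0.13). S phase genes moved without DMSO 3 (0.05). Mitochondrial mRNAs did not pass without DMSO 3 (0.18) and 12 h 1 (0.15). Ribosomal protein genes did not pass without DMSO 1 (-0.053), 2 (-0.046), 12 h 2 (-0.079) and 3 (-0.036), and moved without DMSO 3 (-0.16) and 12 h 1 (-0.13). Nuclear-encoded genes of oxidative phosphorylation passed with replicate number as a block (median 0.056, adjusted p = 0.0487, adjusted p = 0.674 with an estimated correlation) and not without it (0.052, adjusted p = 0.12).

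Between 12 h and 24 h in Ly1, replication-dependent histone genes rose by a median log2 fold change of 0.62, with 25 of 27 members above 0 (adjusted p = 1.61e-06, adjusted p = 0.776 with an estimated correlation). Within replicates 1, 2 and 3 it rose by 0.70, 0.71 and 0.13. Mitochondrially encoded mRNAs rose by a median of 0.49 (adjusted p = 0.000322) but stood at 0.69, 0.77 and -0.14 by replicate. The list stood at 0.25 without 24 h replicate 1. Interferon-stimulated genes rose by 0.29 (0.29, 0.38 and 0.03 by replicate, adjusted p = 0.000543). Leaving out libraries moved its median to 0.45 without 12 h replicate 3. Genes of G2 and mitosis rose further, by a median of 0.18 (0.21, 0.24 and 0.07 by replicate, adjusted p = 0.00162). p53 targets fell, with a median of -0.23 (-0.18, -0.35 and -0.06 by replicate, adjusted p = 0.000543). The fitted median was -0.14 without 24 h replicate 1. For each of these 4 lists the call was lost at an adjusted p = 0.776 with an estimated correlation. MX1 stood at 61.4 ± 10.2 CPM at 24 h against 35.7 ± 10.4 CPM at 12 h (mean ± SD, n = 3 each). Its log2 fold change was 0.78 ± 0.19 (SE, adjusted p = 0.482), and ATF4, the transcription factor of the integrated stress response, had 0.62 ± 0.27 (0.482). Gene by gene, edgeR called 0 genes, with 1446 at an unadjusted p under 0.05 and a smallest adjusted p of 0.218. DESeq2 called 5 and limma voom 0. Leaving out 24 h replicate 3 gave 2780 genes by edgeR.

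Further lists passed between the treated times of Ly1. Ribosomal protein genes had a median of 0.18 (adjusted p = 0.000587), targets of ATF4 0.20 (0.0106) and tubulins 0.19 (0.0463). NF-kappaB targets had 0.23 (0.0463), nuclear-encoded genes of oxidative phosphorylation 0.15 (0.0463) and cholesterol synthesis genes -0.17 (0.0463). With an estimated correlation 0 of the 11 list calls remained (adjusted p = 0.776 to 0.804). Ribosomal protein genes did not pass without 12 h 3 (0.15), 24 h 1 (0.057) and 2 (0.13), and moved without 24 h 3 (0.35). ATF4 targets did not pass without 12 h 1 (0.15), 2 (0.11) and 24 h 3 (0.17). Tubulins did not pass without 12 h 2 (0.14), 3 (0.15), 24 h 1 (0.14) and 2 (0.16). NF-kappaB targets did not pass without 12 h 1 (0.10), 2 (0.11) and 24 h 3 (0.016), and moved without 12 h 3 (0.37). Oxidative phosphorylation genes did not pass without 12 h 2 (0.17), 3 (0.097), 24 h 1 (0.059) and 2 (0.084), and moved without 24 h 3 (0.33). Cholesterol synthesis genes did not pass without 12 h 3 (-0.059), 24 h 1 (-0.057) and 2 (-0.068), and moved without 24 h 3 (-0.44).

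**Figure D3:**
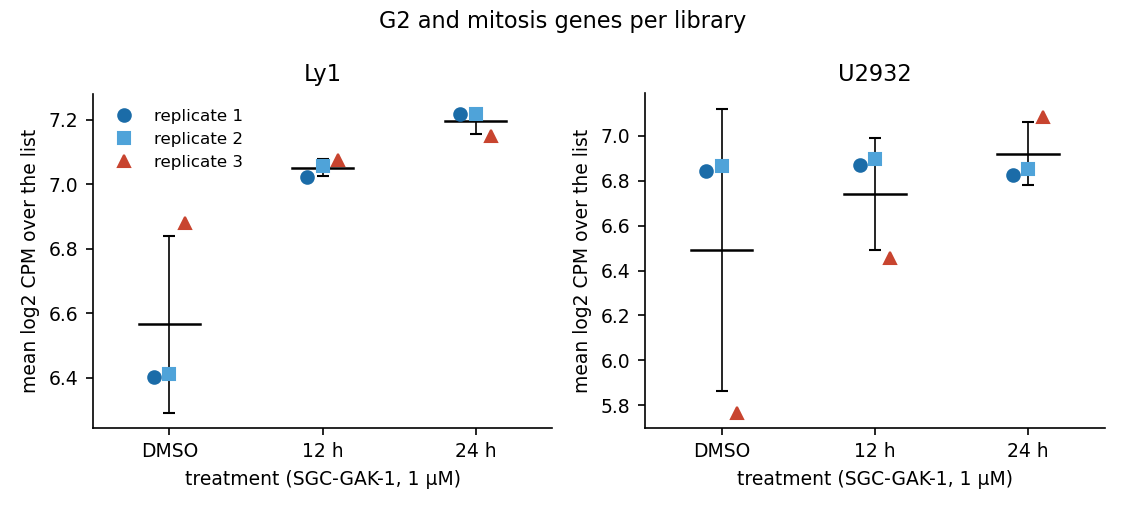
Mean log2 CPM of the G2 and mitosis genes in each library, by line and treatment. Points are libraries, numbered by replicate, and lines with bars are group means ± SD (n = 3). In Ly1 the treated libraries of each replicate number lie above their DMSO library, with median log2 differences at 24 h of 0.83, 0.84 and 0.30, and in U2932 DMSO replicate 3 lies lowest, -1.10 from replicates 1 and 2.

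In U2932, the comparison of 24 h with DMSO asks the same of the ABC line, and genes tied to glycolysis and low oxygen were lower after treatment. Here replicate numbers passed the pairing rule, which cannot tell whether numbers 1 and 2 pair libraries. The genes named were called with replicate number as a block, while the test without the block called 0. ALDOC, aldolase C, fell from 59.86 ± 14.96 to 25.6 ± 4.24 CPM (mean ± SD, n = 3 each), a log2 fold change of -1.22 ± 0.08 (SE, adjusted p = 2.48e-05 with the block and 0.216 without), with -1.04, -1.24 and -1.35 in replicates 1, 2 and 3. NDRG1 (ENSG00000104419.17, chromosome 8, 133237175 to 133302022), a hypoxia-responsive gene, fell with -1.12 ± 0.18, SLC16A3, the lactate exporter MCT4, with -1.02 ± 0.18, and MIR210HG, the host transcript of the hypoxia-induced miR-210, with -0.97 ± 0.24 (adjusted p from 0.01 to 0.0425 with the block). PGK1 (ENSG00000102144.15, chromosome X, 77910739 to 78129295) and SLC2A1, the glucose transporter GLUT1, fell with -0.44 ± 0.06 and -0.28 ± 0.06 (adjusted p = 0.00311 and 0.0234 with the block). The other top falls were NRN1, which encodes neuritin (-1.19 ± 0.19), ELFN2 (-1.08 ± 0.20), RIMKLA (-1.01 ± 0.13) and CD180, a Toll-like receptor relative of B cells (-1.0 ± 0.21). Among the top rises, TUBG2, a gamma-tubulin (ENSG00000037042.9, chromosome 17, 42659284 to 42667006), rose by 0.99 ± 0.17, CCDC150 by 1.26 ± 0.28 and the zinc finger gene ZNF66 by 0.96 ± 0.15. CCDC150 stood at 0.76 with number 3 left out. The remaining top rises, LINC00954, HERC2P2, WASH7P, DDX12P and AGAP4, are a noncoding RNA, pseudogenes and a member of a multi-copy family, whose reads can be shared with related copies or the other strand. Their values of 1.32 ± 0.14, 1.16 ± 0.11, 1.09 ± 0.20, 1.00 ± 0.15 and 0.97 ± 0.20 are uncertain as to source.

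**Figure D4:**
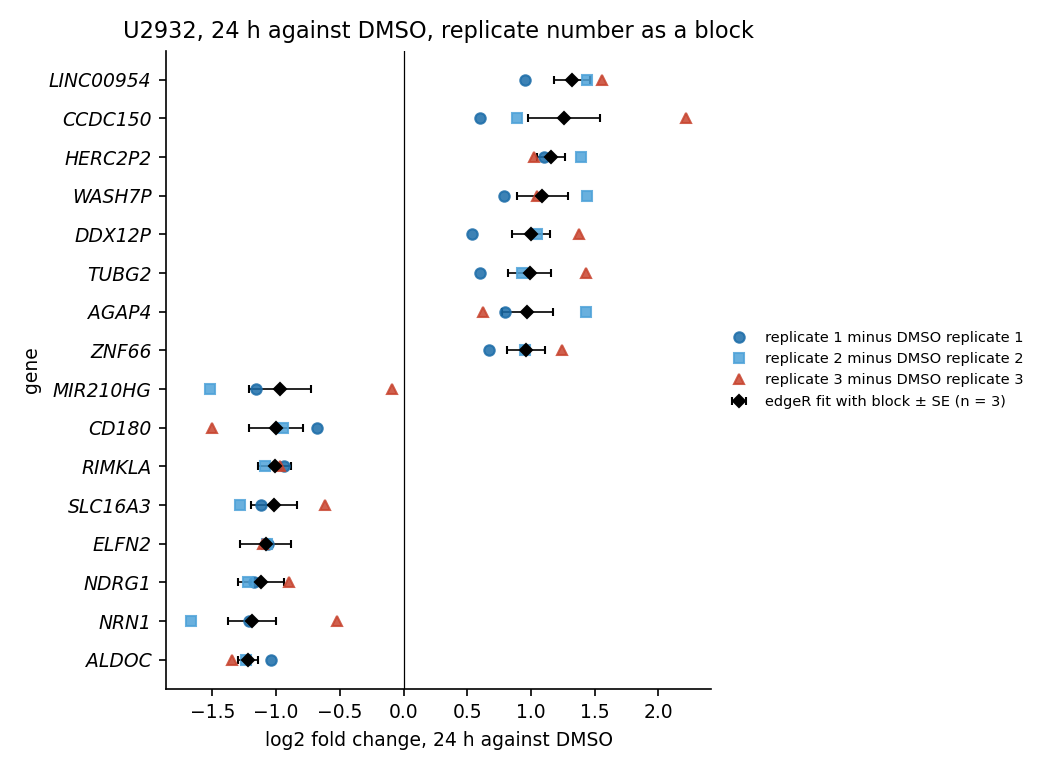
Log2 fold change of the named genes of U2932, 24 h against DMSO, with replicate number as a block. Diamonds with bars are edgeR estimates ± SE (n = 3 per group) and the other points are the differences within each replicate number. Genes were chosen to have a common sign in the 3 replicate numbers. ALDOC was at -1.04, -1.24 and -1.35.

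With the block edgeR called 667 of 15138 genes in U2932 at 24 h, 338 higher and 329 lower. Without it, edgeR called 0 genes, with 1717 at an unadjusted p under 0.05 and a smallest adjusted p of 0.085. DESeq2 called 157 and limma voom 0. Without the block, the edgeR count was 2 without DMSO replicate 1, 4 without DMSO replicate 3 and 1369 without the replicate 3 libraries. With the block, leaving out all libraries of number 1, 2 or 3 gave 84, 1 and 1863 genes, of which 77, 1 and 641 were among the 667, and ALDOC was called each time. Of the germinal centre list 5 of 19 genes were called with the block, all lower, among them SERPINA9, a germinal centre serpin, at -0.68 ± 0.09, S1PR2, a receptor that confines cells to germinal centres, at -0.73 ± 0.10, and GCSAM at -0.51 ± 0.08. Of the plasma cell list 5 of 16 were called, all lower, among them JCHAIN, the joining chain of antibodies, at -0.49 ± 0.10, SDC1 (CD138) at -0.40 ± 0.10, TNFRSF17 (BCMA) at -0.32 ± 0.08 and CD38 at -0.25 ± 0.05, where TNFRSF17 stood at -0.2 with number 3 left out (largest adjusted p 0.0415 with the block). Neither list as a whole passed with an estimated correlation or without DMSO 3, as given below. NFKBIZ, an atypical inhibitor of NF-kappaB, and CFLAR, an inhibitor of caspase 8, rose by 0.62 ± 0.10 and 0.29 ± 0.06 (adjusted p = 0.0101 and 0.0228 with the block). JUND and FOSB, of the AP-1 family, fell with -0.42 ± 0.09 and -0.88 ± 0.18 (adjusted p = 0.024 and 0.0227 with the block).

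As a list, glycolysis and hypoxia genes fell in U2932 at 24 h, with a median of -0.34, 28 of 29 below 0 and -0.31, -0.44 and -0.07 in replicates 1, 2 and 3 (adjusted p = 1.08e-10, adjusted p = 0.479 with an estimated correlation). Of its members 12 were called adjusted over the list alone, and 10 with the block over all genes. Genes of G2 and mitosis had a median of 0.36 (adjusted p = 1.35e-07, adjusted p = 0.681 with an estimated correlation), with 0 members called, and the shift lay in replicate 3, at -0.01, -0.04 and 1.46 in replicates 1, 2 and 3, beside the low level of these genes in DMSO replicate 3. This list did not pass without DMSO 3 (0.063), and moved without DMSO 2 (0.55) and 24 h 3 (0.24). Spindle assembly checkpoint genes stood at 0.37 (0.02, 0.03 and 1.46 by replicate, adjusted p = 0.00427, adjusted p = 0.681 with an estimated correlation). They did not pass without DMSO 3 (0.10). Centrosome genes stood at 0.23 (0.03, 0.01 and 0.78 by replicate, adjusted p = 0.00275, adjusted p = 0.681 with an estimated correlation). The list did not pass without DMSO 3 (0.11) and 24 h 3 (0.16), and moved without DMSO 2 (0.34). Tubulins had 0.24 (0.02, -0.04 and 0.67 by replicate, adjusted p = 0.00275, adjusted p = 0.681 with an estimated correlation). They did not pass without DMSO 3 (0.089).

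Mitochondrially encoded mRNAs fell in U2932 at 24 h, with a median of -0.46, 13 of 13 members below 0 and -0.19, -0.59 and -0.59 in replicates 1, 2 and 3 (adjusted p = 4.62e-06). Its median was -0.27 without 24 h replicate 2 and -0.24 without DMSO replicate 3. With the block 1 member was called, MT-ND3 of complex I at -0.49 ± 0.08. Ribosomal protein genes fell, with a median of -0.13 (-0.07, -0.12 and -0.21 by replicate, adjusted p = 1.13e-06). The median moved to -0.062 without 24 h replicate 3. NF-kappaB targets rose by 0.22 (0.14, 0.21 and 0.21 by replicate, adjusted p = 0.000119). Germinal centre markers fell, with a median of -0.16 (-0.17, -0.16 and -0.12 by replicate, adjusted p = 0.00596). These did not pass without DMSO 3 (-0.057) and 24 h 2 (-0.072), and moved without 24 h 1 (-0.083) and 3 (-0.26). Plasma cell genes fell, with a median of -0.23 (-0.08, -0.07 and -0.37 by replicate, adjusted p = 0.0058). They did not pass without DMSO 3 (-0.13). For these 5 lists the call was lost at an adjusted p = 0.681 with an estimated correlation.

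The other lists past the test in U2932 at 24 h were all lower. Immediate early genes had a median of -0.23 (adjusted p = 0.0014), lysosome genes -0.12 (0.00427), with the protease CTSB at -0.38 ± 0.07 (adjusted p = 0.0156 with the block), histone genes -0.28 (0.0147), interferon-stimulated genes -0.20 (0.0194) and S phase genes -0.083 (0.0147). The S phase call was lost with the block (median -0.082, adjusted p = 0.0548), although MCM5, a subunit of the replicative helicase, was called with it at -0.28 ± 0.07 (adjusted p = 0.0398, and -0.18 with number 3 left out). With an estimated correlation 0 of the 15 list calls remained (adjusted p = 0.479 to 0.733). Lysosome genes did not pass without DMSO 3 (-0.076). Histone genes did not pass without DMSO 1 (0.038) and 24 h 3 (-0.20). Interferon-stimulated genes did not pass without DMSO 1 (-0.16) and 24 h 3 (-0.10). S phase genes did not pass without DMSO 1 (-0.064), 2 (-0.026) and 24 h 3 (-0.032).

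**Figure D5:**
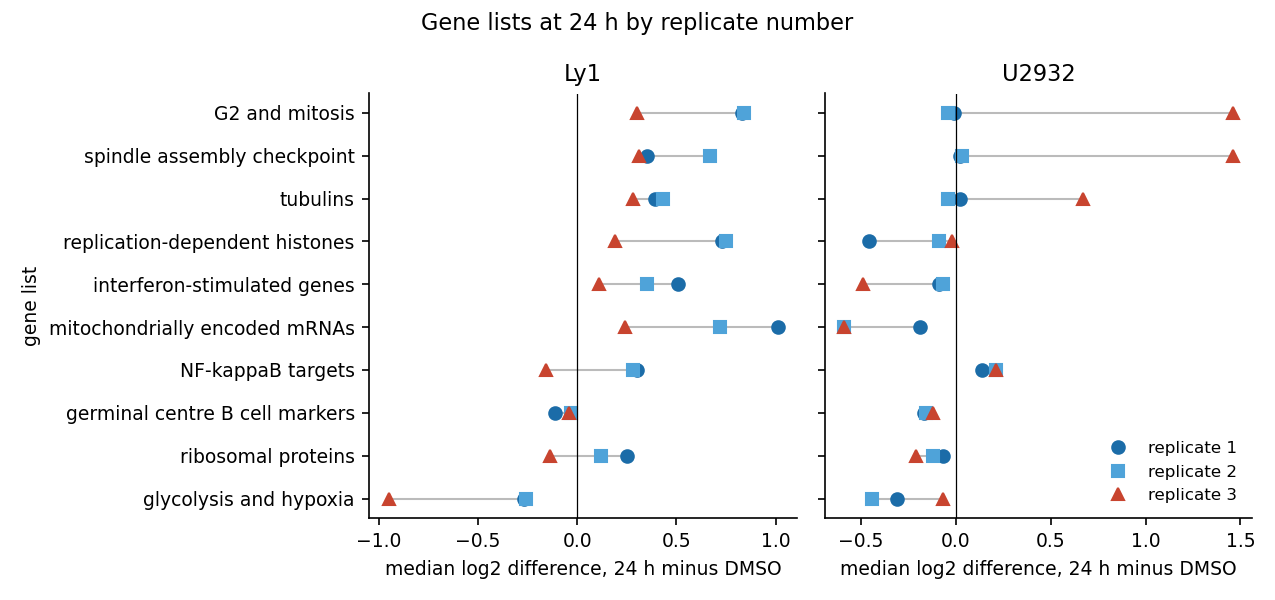
Median log2 difference of 10 gene lists, 24 h minus DMSO, within each replicate number, for Ly1 and U2932. Each point is a median over the genes of a list in a single pair of libraries, without error bars. In U2932 the G2 and mitosis list is at -0.01, -0.04 and 1.46 in replicates 1, 2 and 3, and in Ly1 at 0.83, 0.84 and 0.30.

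At 12 h in U2932 the fall of ALDOC was already present, from 59.86 ± 14.96 to 29.8 ± 3.90 CPM (mean ± SD, n = 3 each), a log2 fold change of -0.99 ± 0.08 (SE, adjusted p = 0.000264 with the block and 0.884 without) and -0.86, -0.93 and -1.17 in replicates 1, 2 and 3. With the block edgeR called 9 genes, all lower, among them NRN1 (-1.28 ± 0.19), C6orf223 (-0.88 ± 0.09), the Wnt ligand gene WNT10A (-0.69 ± 0.08), the receptor gene GPR18 (-0.68 ± 0.11) and KDM4B, a histone demethylase (-0.41 ± 0.06). Without the block, edgeR called 0 genes, with 517 at an unadjusted p under 0.05 and a smallest adjusted p of 0.334. The 517 of 15138 tested genes lie under the share of 0.05 that unchanged genes would give. DESeq2 called 16 and limma voom 0, and leaving out DMSO replicate 3 gave 3 by edgeR. With the block, leaving out the libraries of number 1, 2 or 3 gave 2, 1 and 653. Glycolysis and hypoxia genes fell as a list, with a median of -0.23 (-0.31, -0.39 and -0.10 by replicate), with 27 of 29 below 0 and 11 called adjusted over the list alone (adjusted p = 1.85e-14, adjusted p = 0.535 with an estimated correlation). Cholesterol synthesis genes had a median of -0.22 (adjusted p = 9.39e-08, adjusted p = 0.729 with an estimated correlation), with 0.07, -0.08 and -0.62 by replicate. They did not pass without DMSO 3 (-0.032). For genes of G2 and mitosis the median was 0.19 (0.04, 0.04 and 0.71 by replicate, adjusted p = 4.84e-06, adjusted p = 0.729 with an estimated correlation). The list turned without DMSO 3 (-0.089), and moved without DMSO 1 (0.36), 2 (0.38), 12 h 1 (0.12), 2 (0.11) and 3 (0.34).

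Among the remaining lists past the test in U2932 at 12 h, tubulins had a median of 0.26 (adjusted p = 0.000597), spindle assembly checkpoint genes 0.21 (0.00644), centrosome genes 0.12 (0.0146), ribosome biogenesis genes 0.13 (4.42e-05) and NF-kappaB targets 0.099 (0.00147). S phase genes had 0.07 (7.73e-05), germinal centre markers -0.071 (0.0102) and ribosomal protein genes -0.062 (0.00261). Estimating the correlation left 0 of the 11 list calls (adjusted p = 0.535 to 0.754). Tubulins did not pass without DMSO 3 (0.076). Checkpoint genes did not pass without DMSO 3 (-0.041), 12 h 1 (0.15) and 2 (0.11), and moved without DMSO 1 (0.33), 2 (0.39) and 12 h 3 (0.34). Centrosome genes did not pass without DMSO 3 (-0.067), 12 h 1 (0.11) and 2 (0.075), and moved without DMSO 1 (0.24) and 2 (0.19). Ribosome biogenesis genes did not pass without DMSO 3 (0.041), and moved without 12 h 2 (0.071) and 3 (0.21). NF-kappaB targets did not pass without 12 h 3 (0.042). S phase genes did not pass without DMSO 3 (0.047) and 12 h 3 (0.05), and moved without DMSO 1 (0.11) and 2 (0.11). Germinal centre markers did not pass without DMSO 3 (0.007), 12 h 1 (-0.062) and 2 (-0.026), and moved without DMSO 1 (-0.13), 2 (-0.15) and 12 h 3 (-0.24). Ribosomal protein genes did not pass without DMSO 2 (-0.037) and 12 h 3 (0.02), and moved without DMSO 3 (-0.095), 12 h 1 (-0.12) and 2 (-0.099). With the block, nuclear-encoded genes of oxidative phosphorylation (0.06, adjusted p = 0.02) and mitochondrially encoded mRNAs (-0.13, adjusted p = 0.0319) also passed, and without it they had 0.057 (0.0718) and -0.15 (0.0837). With an estimated correlation these calls ended (adjusted p = 0.694 and 0.694).

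Between 12 h and 24 h in U2932, S phase genes fell as a list, with a median of -0.17, 44 of 50 below 0 and -0.07, -0.15 and -0.31 in replicates 1, 2 and 3 (adjusted p = 3.56e-09, adjusted p = 0.858 with an estimated correlation), and with the block 18 were called adjusted over the list alone and 0 over all genes. Cholesterol synthesis genes rose by a median of 0.24 (0.12, 0.24 and 0.36 by replicate, adjusted p = 3.38e-06, adjusted p = 0.858 with an estimated correlation). Mitochondrially encoded mRNAs fell, with a median of -0.29 (-0.15, -0.68 and -0.19 by replicate, adjusted p = 0.000545, adjusted p = 0.858 with an estimated correlation). It no longer passed without 24 h replicate 2 (median -0.10, adjusted p = 0.163). With the block edgeR called 151 genes, 115 higher and 36 lower. MT2A, a metallothionein (ENSG00000125148.7, chromosome 16, 56608584 to 56609497), fell from 7.38 ± 0.473 to 3.17 ± 0.243 CPM (mean ± SD, n = 3 each). Its log2 fold change was -1.22 ± 0.20 (SE, adjusted p = 0.0183 with the block), and LDLRAD4 and the cathepsins CTSO and CTSB fell with -0.88 ± 0.13, -0.80 ± 0.17 and -0.49 ± 0.07. The top rises, OLMALINC (1.08 ± 0.14), LINC00954 (0.98 ± 0.13), HERC2P2 (1.07 ± 0.11), WASH7P (1.16 ± 0.20) and DDX12P (1.02 ± 0.15), are noncoding RNAs and pseudogenes, whose reads are uncertain as to source. Without the block, edgeR called 0 genes, with 1274 at an unadjusted p under 0.05 and a smallest adjusted p of 0.296. DESeq2 called 74 and limma voom 0, and with the block leaving out the libraries of number 1, 2 or 3 gave 1, 0 and 1503.

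Smaller falls in U2932 from 12 h to 24 h were measured for lysosome genes (-0.12, adjusted p = 0.00516), ribosomal protein genes (-0.068, 0.00654), immediate early genes (-0.18, 0.0118), ribosome biogenesis genes (-0.065, 0.0169), interferon-stimulated genes (-0.15, 0.0176) and plasma cell genes (-0.11, 0.0267). Estimating the correlation left 0 of the 9 list calls (adjusted p = 0.635 to 0.858). Lysosome genes moved without 12 h 3 (-0.052). Ribosomal protein genes did not pass without 12 h 1 (-0.016), 2 (-0.044) and 24 h 3 (0.002), and moved without 12 h 3 (-0.15) and 24 h 1 (-0.12). Immediate early genes did not pass without 12 h 3 (-0.043) and 24 h 3 (-0.15). Ribosome biogenesis genes did not pass without 12 h 1 (-0.06), 2 (-0.008) and 24 h 3 (0.017), and moved without 12 h 3 (-0.15), 24 h 1 (-0.12) and 2 (-0.17). Interferon-stimulated genes did not pass without 12 h 1 (-0.17) and 24 h 3 (-0.15). Plasma cell genes did not pass without 12 h 1 (-0.079), 3 (-0.062) and 24 h 3 (-0.087).

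The difference between the lines in their response at 24 h was tested directly, as U2932 minus Ly1. Mitochondrially encoded mRNAs differed most, with a median of -1.15 and 13 of 13 members below 0, all 13 called adjusted over the list alone (adjusted p = 1.02e-13, adjusted p = 0.306 with an estimated correlation). MT-ATP8 stood at -1.79 ± 0.40 and MT-ND3 at -1.31 ± 0.31 (SE), but 0 members were called over all genes (adjusted p = 0.274 and 0.288). Replication-dependent histone genes had a median difference of -0.89 with 36 of 36 below 0 (adjusted p = 1.52e-10, adjusted p = 0.262 with an estimated correlation). Interferon-stimulated genes had -0.55 (adjusted p = 1.48e-07, adjusted p = 0.0286 with an estimated correlation). The median became -0.88 without Ly1 DMSO replicate 3. Scaling by library size alone moved the median of all genes in this difference from -0.003 to 0.14. SLC7A5, an amino acid transporter that ATF4 activates (ENSG00000103257.9, chromosome 16, 87830023 to 87869507), and GINS2, of the replicative helicase, had -0.65 ± 0.17 and -0.59 ± 0.11 (adjusted p = 0.317 and 0.183). The G2 and mitosis list differed by a median of -0.27 (adjusted p = 0.00377, adjusted p = 0.98 with an estimated correlation). The list did not pass without Ly1 DMSO 2 (-0.20), U2932 DMSO 1 (-0.11) and 2 (-0.10), and moved without Ly1 DMSO 1 (-0.16), 3 (-0.43) and U2932 DMSO 3 (-0.56). Gene by gene, edgeR called 0 genes, with 1348 at an unadjusted p under 0.05 and a smallest adjusted p of 0.089. DESeq2 called 56 and limma voom 0. Fits of this difference with the block, which change this count and the interferon call, are given with the processing at the end. Leaving out Ly1 24 h replicate 3, Ly1 DMSO replicate 3 or U2932 24 h replicate 3 gave 591, 8 and 1 genes.

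Ribosomal protein genes differed at 24 h by a median of -0.25 (adjusted p = 1.74e-06), heat shock genes by -0.30 (0.000169), ATF4 targets by -0.29 (0.000248), nuclear-encoded genes of oxidative phosphorylation by -0.21 (0.00564), S phase genes by -0.13 (0.00718), immediate early genes by -0.55 (0.00718) and lysosome genes by -0.12 (0.0175). Their calls were lost with an estimated correlation (adjusted p = 0.645 to 0.98). Ribosomal protein genes moved without Ly1 24 h 1 (-0.10), 2 (-0.14) and U2932 24 h 3 (-0.14). Heat shock genes did not pass without Ly1 DMSO 3 (-0.17). Oxidative phosphorylation genes did not pass without Ly1 DMSO 3 (-0.11), Ly1 24 h 1 (-0.088), 2 (-0.094) and U2932 DMSO 1 (-0.19), and moved without U2932 24 h 3 (-0.13). S phase genes did not pass without Ly1 DMSO 3 (-0.096), Ly1 24 h 3 (-0.046), U2932 DMSO 2 (-0.10) and U2932 24 h 3 (-0.083), and moved without Ly1 24 h 2 (-0.083) and U2932 24 h 2 (-0.085). Immediate early genes did not pass without Ly1 24 h 3 (0.061) and U2932 DMSO 3 (-0.25), and moved without Ly1 DMSO 1 (-0.25). Lysosome genes did not pass without Ly1 DMSO 3 (-0.097), Ly1 24 h 3 (-0.068), U2932 DMSO 3 (-0.028) and U2932 24 h 2 (-0.044), and moved without U2932 DMSO 1 (-0.19). At 12 h, cholesterol synthesis genes differed most, by a median of -0.44 with 23 of 24 below 0 (adjusted p = 1.5e-11, adjusted p = 0.608 with an estimated correlation), and MVD, mevalonate diphosphate decarboxylase, had -0.60 ± 0.20 (SE, adjusted p = 1). The list stood at -0.23 without U2932 DMSO replicate 3. Genes of G2 and mitosis differed at 12 h by -0.28 (adjusted p = 4.64e-05), mitochondrially encoded mRNAs by -0.39 (0.000673), histone genes by -0.23 (0.0487) and heat shock genes by -0.22 (0.000894). Also p53 targets differed by -0.19 (0.0264), germinal centre markers by -0.14 (0.0264), NF-kappaB targets by 0.11 (0.0281), ribosome biogenesis genes by 0.11 (0.0494) and B cell identity genes by -0.067 (0.0494). Estimating the correlation left 0 of the 10 calls (adjusted p = 0.573 to 0.926). With the block, histone genes (-0.21, adjusted p = 0.157) and NF-kappaB targets (0.097, adjusted p = 0.0703) no longer passed. G2 and mitosis genes did not pass without U2932 DMSO 1 (-0.13), 2 (-0.099) and U2932 12 h 3 (-0.17), and moved without Ly1 DMSO 1 (-0.18), 3 (-0.44) and U2932 DMSO 3 (-0.55). Mitochondrial mRNAs did not pass without Ly1 DMSO 3 (-0.32) and U2932 DMSO 3 (-0.20). Histone genes did not pass without Ly1 DMSO 3 (-0.21), Ly1 12 h 1 (-0.30), 2 (-0.20), U2932 DMSO 1 (-0.099), 2 (-0.26), U2932 12 h 2 (-0.29) and 3 (-0.25), and moved without U2932 DMSO 3 (-0.38). Heat shock genes did not pass without Ly1 DMSO 3 (-0.069) and U2932 DMSO 3 (-0.13), and moved without Ly1 DMSO 2 (-0.33) and U2932 DMSO 1 (-0.33). The p53 targets did not pass without Ly1 DMSO 1 (-0.16), 2 (-0.15), U2932 DMSO 3 (-0.057), U2932 12 h 1 (-0.17) and 2 (-0.15), and moved without Ly1 12 h 2 (-0.12). Germinal centre markers did not pass without Ly1 DMSO 1 (-0.12), 2 (-0.15), U2932 DMSO 3 (-0.038), U2932 12 h 1 (-0.09) and 2 (-0.056), and moved without Ly1 DMSO 3 (-0.23), Ly1 12 h 2 (-0.093), U2932 DMSO 2 (-0.22) and U2932 12 h 3 (-0.28). NF-kappaB targets did not pass without Ly1 DMSO 3 (-0.14), Ly1 12 h 1 (0.077), 2 (0.072), U2932 DMSO 3 (0.10) and U2932 12 h 3 (0.011), and moved without Ly1 DMSO 1 (0.26), 2 (0.22), Ly1 12 h 3 (0.22), U2932 12 h 1 (0.18) and 2 (0.18). Ribosome biogenesis genes did not pass without Ly1 DMSO 1 (0.095), 2 (0.054), Ly1 12 h 1 (0.08), 3 (0.078), U2932 DMSO 3 (0.032), U2932 12 h 1 (0.096) and 2 (0.052), and moved without Ly1 DMSO 3 (0.19). B cell identity genes did not pass without Ly1 DMSO 1 (-0.068), 3 (-0.10), Ly1 12 h 1 (-0.047), 2 (-0.013), U2932 DMSO 1 (-0.057), 2 (-0.058), 3 (-0.062), U2932 12 h 1 (-0.087), 2 (-0.059) and 3 (-0.13). Over single genes at 12 h edgeR called 0 genes, with 404 at an unadjusted p under 0.05 and a smallest adjusted p of 0.881. DESeq2 called 1 and limma voom 0, and leaving out Ly1 DMSO replicate 3 gave 4 by edgeR.

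Without treatment, U2932 expressed NF-kappaB and activated B cell genes at higher levels than Ly1. NF-kappaB targets were higher by a median log2 difference of 2.94 with 22 of 23 called (adjusted p = 1.8e-08, adjusted p = 0.165 with an estimated correlation), such as BCL2A1, an anti-apoptotic BCL2 relative (6.67 ± 0.25), and the adhesion molecule ICAM1 (3.61 ± 0.16). Activated B cell type markers were higher by 1.71 with 17 of 20 called higher (adjusted p = 1.12e-05), a call that held with an estimated correlation (adjusted p = 0.0346). Plasma cell genes were higher by 3.32 (adjusted p = 0.000231, adjusted p = 0.103 with an estimated correlation), with SDC1 at 7.11 ± 0.28 and TNFRSF17 at 5.29 ± 0.14. Immediate early genes were higher by 2.58 (adjusted p = 1.12e-05, adjusted p = 0.179 with an estimated correlation), with the nuclear receptor NR4A1 at 5.07 ± 0.28. Histone genes were higher by 1.68 and ATF4 targets by 0.50 (adjusted p = 0.000235 and 0.0224, adjusted p = 0.643 and 0.992 with an estimated correlation), and ribosomal protein genes were lower, with a median of -0.43, with RPL8 at -1.43 ± 0.13 (adjusted p = 0.000235 for the list, adjusted p = 0.992 with an estimated correlation).

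Several genes had 0 counts in the DMSO libraries of a line, so that their differences are lower bounds against 3 counts over the 3 libraries of that group. Relative to Ly1, IGHV4-39, an immunoglobulin variable gene, was at least 42740-fold higher in U2932, CDH2, N-cadherin (ENSG00000170558.10, chromosome 18, 27932879 to 28177946), at least 30640-fold, HLA-DPA1, an MHC class II chain, at least 4466-fold, and CREB3L2, a transcription factor of the secretory pathway, at least 4381-fold. Relative to U2932, GTSF1 (ENSG00000170627.11, chromosome 12, 54455950 to 54473602) was at least 2068-fold higher in Ly1, CYB5A, cytochrome b5, at least 1720-fold, and AGR2, a protein disulfide isomerase, at least 1228-fold. RB1 was higher in U2932 by 2.62 ± 0.16 (log2, SE) and the CDK inhibitor CDKN1A by 1.65 ± 0.17 (adjusted p = 5.16e-11 and 9.24e-08). In all, edgeR called 10207 of 16191 genes between the lines, 5358 higher and 4849 lower in U2932. The lines were also grown in different media, IMDM for Ly1 and RPMI for U2932, which the comparison cannot separate from the lines.

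Across genes, the effects at 12 h and 24 h correlated within Ly1 with r = 0.573 (covariance 0.0608) and within U2932 with r = 0.499 (covariance 0.0357), where genes are not independent replicates. Both times share their DMSO libraries, and simulated groups without any change gave r = 0.495 ± 0.015 (SD, covariance 0.0355) in Ly1 and 0.495 ± 0.016 (covariance 0.0422) in U2932. The observed r lies above the simulated one in Ly1 and within its SD in U2932. The simulated libraries were drawn independently, without the link between libraries of the same number, and the simulated covariance in U2932 exceeds the one observed, so these values are only a rough guide. Leaving out single libraries moved r in Ly1 from 0.451 (24 h replicate 3) to 0.712 (DMSO replicate 3), and in U2932 from 0.342 (12 h replicate 1) to 0.642 (DMSO replicate 1). Between the lines, which share no libraries, r was 0.233 at 12 h and 0.258 at 24 h, and at 12 h it was 0.051 without Ly1 DMSO replicate 3.

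Lists that did not pass in either line at 24 h include the G1 to S regulators of the RB and E2F axis, with medians of -0.056 in Ly1 and -0.016 in U2932 (adjusted p = 0.646 and 0.877), the unfolded protein response, with -0.11 in Ly1 and -0.065 in U2932 (adjusted p = 0.243 and 0.302), the BCL2 family, with -0.022 in Ly1 and -0.098 in U2932 (adjusted p = 0.713 and 0.309), and coenzyme Q synthesis, with 0.15 in Ly1 and 0.082 in U2932 (adjusted p = 0.394 and 0.797). B cell identity genes had -0.001 in Ly1 and -0.045 in U2932 (adjusted p = 0.882 and 0.447) and activated B cell type markers -0.052 in Ly1 and -0.032 in U2932 (adjusted p = 0.743 and 0.877). Markers of T and NK cells had -0.12 in Ly1 and -0.087 in U2932 (adjusted p = 0.774 and 0.971), and their most abundant gene, LCK, a kinase also expressed by some B cell lines, averaged 154.5 CPM in Ly1 and 32.0 CPM in U2932. Too few markers of myeloid, fibroblast and endothelial, and epithelial cells were expressed for a test. The most abundant of them were AIF1 at 2.16 and 0.756 CPM, PECAM1 at 3.37 and 2.72 CPM, and EPCAM at 4.44 and 32.4 CPM, in Ly1 and U2932.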

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

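The patterns weighed below were picked from the results, so no test of them counts as planned. Of the splits, only those without the block were planned.

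The responses of the lines differed in a direct test (camera, U2932 minus Ly1) for 21 list results. At 12 h the median log2 differences were -0.28 for genes of G2 and mitosis, -0.23 for replication-dependent histones, -0.19 for p53 targets, -0.44 for cholesterol synthesis, -0.22 for the heat shock response, 0.11 for NF-kappaB targets, 0.11 for ribosome biogenesis, -0.067 for B cell identity, -0.14 for germinal centre markers and -0.39 for mitochondrially encoded mRNAs. At 24 h they were -0.13 for S phase, -0.27 for G2 and mitosis, -0.89 for histones, -0.12 for lysosome genes, -0.29 for ATF4 targets, -0.30 for heat shock, -0.55 for immediate early genes, -0.55 for interferon-stimulated genes, -0.25 for ribosomal proteins, -0.21 for nuclear-encoded oxidative phosphorylation genes and -1.15 for mitochondrially encoded mRNAs. Of these the interferon-stimulated genes alone passed with an estimated correlation (adjusted p = 0.0286), and with the block added they did not, as given in the next part.

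The first pattern weighed is that the replicate 3 libraries stand apart, in U2932 with 20 genes at least 4-fold lower in all 3 groups, and in Ly1 with r = -0.15 between the 24 h changes of replicates 1 and 3. Transcript length as the source is argued against by a Spearman rho of 0.046 over 15018 genes of U2932, while GC content, with a rho of -0.112, fell between the limits set for and against it and stays open. A processing step shared by the replicate 3 libraries of both lines would move the same genes in both, but across 13054 genes, which are not independent replicates, the shifts of replicate 3 in DMSO correlated with r = -0.116. An exchange of the Ly1 DMSO and 24 h libraries of replicate 3, the split that called 160 genes, stays open. The r of -0.15 is far from the 0.92 between replicates 1 and 2 and from its mirror image. Also open for U2932, a line described as holding subclones, is a lower share of a second population of cells, since 29 genes picked on DMSO had a median of -2.81 at 24 h with 0 genes higher, though a change in all cells of that culture predicts the same.

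The second pattern is that mitochondrially encoded mRNAs were higher in Ly1 and lower in U2932 at 24 h. The scaling as its source is argued against by a median difference of -0.999 with library size only, and the replicate 3 libraries alone by -1.23 without them. A candidate explanation that stays open is a general change in how much mitochondrial RNA entered the libraries, by biology or by preparation, because the 2 mitochondrial ribosomal RNAs moved along by a mean of -1.0 (MT-RNR1 -1.02 ± 0.53 and MT-RNR2 -0.98 ± 0.39, SE, adjusted p = 0.625 and 0.51). Different responses of the lines to the inhibitor may also underlie it and were not tested apart from this.

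The third pattern is that glycolysis and hypoxia genes were lower at 24 h in both lines. A GC or length trend as the whole source is argued against by corrected medians of -0.51 in Ly1 and -0.369 in U2932. The replicate 3 libraries alone are argued against by medians of -0.242 in Ly1 and -0.42 in U2932 without them. For Ly1 this is weaker, at -0.11 without DMSO 3 only. A loss of counts by abundant genes in general is argued against by 10000 random lists of matched expression, whose 2.5th percentile was -0.08 in Ly1 and -0.087 in U2932. A response to the inhibitor and culture density or medium at harvest, which the labels do not give, stay open in both lines. They were not tested apart.

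The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. In Ly1 at 12 h, U2932 at 12 h and 24 h, and 24 h against 12 h in each line, the real split called 0 genes by edgeR and so did the other splits, so 10 of 10 were as large by construction. In these 5 comparisons DESeq2 called 94, 16, 157, 5 and 74 genes, and limma voom 0 in each. In Ly1 at 24 h the real split called 77 and the highest other 160, so 2 of 10 were as large. That other split sets DMSO replicates 1 and 2 with 24 h replicate 3 against the rest, which points to the structure of the replicate 3 libraries. Between the lines in DMSO the real split called 10207 and the highest other 59, so 1 of 10. For the differences between lines the real count was 0, so 24 of 24 splits drawn were as large by construction and decide nothing, with a highest other of 0 at 12 h and 4 at 24 h. With the block, the 4 splits that part all replicate numbers gave highest other counts of 0 beside the real 667 in U2932 at 24 h, 9 at 12 h and 151 for 24 h against 12 h, each 1 of 4. In Ly1 at 12 h, and for 24 h against 12 h, the real count with the block was 0, so 4 of 4 were as large by construction. Ly1 at 24 h, where the numbers did not pass the pairing rule, is in the next part.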

How the results depend on the processing

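The tests chosen after seeing the data were those without the replicate 3 libraries, with a term for the replicate 3 set, with the block in limma voom or DESeq2 or together with an estimated correlation, with all libraries of a number left out, and with the number shared across lines. For the agreement between comparisons they were all those but the stricter filter and the scaling. The number of genes called without any alternative was 0 except for 77 in Ly1 at 24 h and 10207 between the lines in DMSO, and counts within 1.5 times of these under an alternative are not repeated here.

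Counts of genes stayed within 1.5 times with DESeq2's size factors, the filter of at least 1 CPM and limma voom, and moved in some comparisons with the other choices. Without a filter on low counts edgeR called 200 for Ly1 12 h, 794 for Ly1 24 h and 211 for Ly1 24 h against 12 h. In U2932 it was 2 for 12 h, 57 for 24 h and 24 for 24 h against 12 h. The difference between lines gave 21 at 12 h and 129 at 24 h. DESeq2 called 94 for Ly1 12 h, 573 for Ly1 24 h and 5 for Ly1 24 h against 12 h. U2932 gave 16 for 12 h, 157 for 24 h and 74 for 24 h against 12 h. For the difference between lines it was 1 at 12 h and 56 at 24 h. A required 2-fold change, which can only remove calls, left 22 for Ly1 24 h and 5756 for the lines in DMSO. Library size as the only scaling left 1 for Ly1 24 h, a fall, against 48 rises and 29 falls. Fits of the 2 compared groups, which have fewer libraries, gave 1 for Ly1 12 h and 0 for Ly1 24 h. With replicate number as a block edgeR called 275 for Ly1 24 h. For U2932 the count was 9 for 12 h, 667 for 24 h and 151 for 24 h against 12 h. Differences between lines numbered 45 at 24 h. Limma voom with the block called 269 for Ly1 24 h. U2932 had 3 for 12 h, 484 for 24 h and 89 for 24 h against 12 h. Responses of the lines differed for 3 at 12 h and 45 at 24 h. DESeq2 with the block called 116 for Ly1 12 h, 727 for Ly1 24 h and 35 for Ly1 24 h against 12 h. In U2932 it was 45 for 12 h, 716 for 24 h and 261 for 24 h against 12 h. The difference between lines gave 15 at 12 h and 274 at 24 h. In Ly1 between DMSO and 24 h the numbers did not pass the pairing rule (correlations of 0.073 to 0.211). There the split of DMSO replicates 1 and 2 with 24 h replicate 3 against the rest called 1473 with the block, against the 275 of the real split, and in each line all libraries but 24 h replicate 2 correlated best with their own number. A term for the replicate 3 set gave 27 for Ly1 12 h and 716 for Ly1 24 h. U2932 gave 34 for 12 h, 916 for 24 h and 218 for 24 h against 12 h. For the difference between lines it was 4 at 12 h and 146 at 24 h. Without the replicate 3 libraries, which also lowers the spread between replicates, the counts were 1262 for Ly1 12 h, 6483 for Ly1 24 h and 5841 for Ly1 24 h against 12 h. For U2932 the count was 434 for 12 h, 1369 for 24 h and 940 for 24 h against 12 h. Differences between lines numbered 729 at 12 h and 4318 at 24 h. With the block and number 1 left out they were 6 for Ly1 24 h. U2932 had 2 for 12 h, 84 for 24 h and 1 for 24 h against 12 h. Leaving out number 2 gave 2 for Ly1 24 h, 1 for U2932 12 h and 1 for U2932 24 h. Leaving out number 3 gave 1448 for Ly1 12 h, 6695 for Ly1 24 h and 6027 for Ly1 24 h against 12 h. In U2932 it was 653 for 12 h, 1863 for 24 h and 1503 for 24 h against 12 h. With the block, 19 genes fell in both lines at 24 h, ALDOC among them, against 2.19 expected from the numbers called, and 4 rose in both, against 3.78 expected. Apart from the fewer libraries or calls named, the cause of these shifts was not tested.

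The number of lists past the test was 11 for Ly1 12 h, 11 for Ly1 24 h, 11 for Ly1 24 h against 12 h, 11 for U2932 12 h and 15 for U2932 24 h. It was 9 for U2932 24 h against 12 h, 10 for the difference between lines at 12 h, 11 for the difference between lines at 24 h and 7 for the lines in DMSO. A correlation estimated per list, in place of the preset one, left 1 for the difference between lines at 24 h and 1 for the lines in DMSO and 0 for the others. The rotation test fry gave 2 for Ly1 12 h, 4 for Ly1 24 h, 1 for the difference between lines at 24 h and 16 for the lines in DMSO and 0 for the others. With an estimated correlation and the block 0 lists passed in all 8 treatment comparisons, with adjusted p = 0.0869 for interferon-stimulated genes in the difference at 24 h, and with a term for the replicate 3 set 2 passed for the difference between lines at 24 h and 0 for the other 7. Without the replicate 3 libraries the number changed by over 1.5 times in U2932 at 12 h, to 7. Over single lists, the preset correlation with DESeq2's size factors kept 109 of 111 results in their direction and on their side of the threshold, library size only 104, and the block 97 of 101. Apart from the changes printed beside the results, the block changed no other call of a list where the numbers passed the pairing rule. In Ly1 at 24 h, where they did not, NF-kappaB targets passed with the block (median 0.28, adjusted p = 0.0117).

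The direction of the test, which need not be the sign of the median, changed for some lists. Without the replicate 3 libraries, S phase genes stood at -0.012 (adjusted p = 0.631) in Ly1 at 24 h, and genes of G2 and mitosis at -0.023 (adjusted p = 0.232) in U2932 at 24 h, -0.074 (adjusted p = 0.00125) in U2932 between 12 h and 24 h, and 0.54 (adjusted p = 0.000343) between the lines in DMSO. In the difference between lines at 12 h, heat shock genes stood at 0.052 (adjusted p = 0.527), NF-kappaB targets at -0.042 (adjusted p = 0.18) and G1 to S regulators at 0.012 (adjusted p = 0.819). At 24 h lysosome genes stood at -0.021 (adjusted p = 0.923) and G1 to S regulators at 0.17 (adjusted p = 0.0537). G1 to S regulators, which passed in neither difference, also turned at 24 h with DESeq2's size factors, at -0.009 (adjusted p = 0.982), and library size only, at 0.11 (adjusted p = 0.832). They also turned with the block, at -0.038 (adjusted p = 0.988), and adjusted p = 0.994 with an estimated correlation, and the term for replicate 3, at -0.038 (adjusted p = 0.962), and 0.987 with an estimated correlation. At 12 h they turned with that term, at -0.012 (adjusted p = 1) with either correlation. S phase genes turned in the difference at 12 h with library size only, at 0.016 (adjusted p = 0.879). Between the lines in DMSO the rotation test put S phase genes at -0.09 (adjusted p = 0.935) and G2 and mitosis genes at 0.046 (adjusted p = 0.935), where the direction is the test's own. The cause of the other changes was not tested.

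With each library left out in turn, counts of genes ranged from 0 to 88 for Ly1 12 h, 0 to 3030 for Ly1 24 h and 0 to 2780 for Ly1 24 h against 12 h. They ranged from 0 to 3 for U2932 12 h, 0 to 4 for U2932 24 h, 0 to 4 for the difference between lines at 12 h and 0 to 591 for the difference between lines at 24 h. Counts of lists ranged from 7 to 10 for Ly1 24 h against 12 h, 9 to 15 for U2932 24 h, 5 to 10 for U2932 24 h against 12 h and 5 to 10 for the difference between lines at 12 h. Medians of lists whose direction changed ranged from -0.083 to 0.075 for G1 to S regulators, -0.14 to 0.26 for NF-kappaB targets, 0.032 to 0.19 for ribosome biogenesis genes and -0.08 to 0.022 for S phase genes, all for the difference between lines at 12 h. At 24 h that for G1 to S regulators ranged from -0.09 to 0.11. In Ly1 they ranged from -0.014 to 0.048 for G1 to S regulators at 12 h, and from -0.15 to 0.015 for G1 to S regulators and -0.016 to 0.084 for S phase genes at 24 h. In U2932 at 12 h they ranged from -0.067 to 0.24 for centrosome genes, -0.089 to 0.38 for genes of G2 and mitosis, -0.12 to 0.02 for ribosomal protein genes and -0.041 to 0.39 for spindle checkpoint genes, and at 24 h from -0.055 to 0.012 for G1 to S regulators. Between the lines in DMSO they ranged from -0.14 to 0.37 for genes of G2 and mitosis. The correlation of effects ranged from 0.451 to 0.712 for 12 h and 24 h in Ly1, 0.342 to 0.642 in U2932, 0.051 to 0.242 between the lines at 12 h and 0.192 to 0.273 at 24 h. Between the lines it was 0.304 at 12 h and 0.299 at 24 h with the stricter filter, and 0.06 and 0.193 without the replicate 3 libraries. Where leaving out a library left 2 in a group, the spread was pooled over the groups of the fit.

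Of the 99 named gene results, 601 of 771 values kept their direction and side of the threshold under the alternatives planned before the data were examined, 59 fell short of it and 111 passed it newly, with 0 in the other direction. With each library left out the numbers were 518, 100 and 12 of 630, and under those chosen later 172, 0 and 194 of 366. Of the list results those alternatives kept 353 of 545 values, with 185 short of the threshold, 1 newly past it and 6 in the other direction, and leaving out each library kept 641 of 810, with 138, 6 and 25 in those classes. Alternatives chosen later kept 206 of 424, with 201, 3 and 14. Depth limited little of this, since 3 counts stand for at most 0.133 CPM and the named genes have at least 5 CPM in the higher group.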
